A study of Mus musculus with 4 samples.

How the data were processed

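Gene expression was measured by RNA sequencing in 4 libraries of pancreatic β cells from mouse neonates at day 13. Per the labels' protocols, islets were digested from the pancreas and purified on a density gradient, and dissociated cells were sorted by flow cytometry for mCherry, a nuclear reporter switched on by a Cre recombinase driven from Ucn3, a gene of maturing β cells. Full-length cDNA was made from low-input RNA with the SMART-Seq v4 kit and turned into libraries by Nextera XT tagmentation, a chemistry that does not mark the strand. The labels give 2 control libraries with intact Robo1 and Robo2, and 2 Robo mutant libraries with a homozygous Robo1 deletion allele and homozygous conditional Robo2 alleles. Both genotypes are heterozygous for Ucn3-Cre and for the mCherry reporter. The Robo1 allele is given as deleted and not as conditional, so its loss is not confined to cells with Cre. Deletion of Robo2 depends on the Cre. Replicate numbers follow accession order and pair nothing. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

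Per the submitters' processing notes, the tools named are bcl2fastq 2.20.0.422, STAR 2.5.3a, RSEM 1.3.0 and edgeR 3.16.5, and the genome build is GRCm38. The role of edgeR and the annotation release are not given in the sources used here. The deposited table holds an estimated count for each of 51912 genes in each library, the gene-level expected counts that RSEM gives, in whole numbers. The table's own name calls its values normalized. Its columns nevertheless sum to different totals, from 38886129 to 49593712, and neither TMM, RLE nor upper-quartile factors brought the libraries to an equal effective size (largest over smallest 1.23, 1.21 and 1.20, against 1.28 for the totals). The values were therefore treated as estimated counts, although an earlier rescaling of each library cannot be excluded. If there was one, the totals are not the sequencing depth and counting intervals are approximate. No column of another sample was present (0 columns).

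The design, the gene lists and the rule for named genes were fixed before the data were examined. The design named limma for normalized values and edgeR's quasi-likelihood test for counts, and the second was used because of the unit. Values, already whole, were rounded to whole numbers, genes with at least 10 counts in at least 2 libraries were kept (16517 genes), and TMM factors were computed with edgeR 4.0.16 in R 4.3.3. Genes were tested two-sided with glmQLFit and glmQLFTest, Robo mutant against control, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values use the TMM-scaled totals, and errors of CPM are standard deviations over 2 libraries. Of the 28 lists, 25 were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2(TMM-scaled count + 1). By the design the targeted genes and the sex-linked genes were described and not tested as sets, and the erythroid list had 0 tested members. Camera compares a list with the other tested genes, so the direction it gives is relative to them. Camera with an estimated correlation and fry were run beside the preset correlation. A list's median was also placed among the medians of 10000 random lists matched on mean CPM. Chromosome 16, without Robo1 and Robo2, was compared with other autosomes by Fisher's exact test at an unadjusted p under 0.01.

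Positions and names came from GENCODE M21, which is on the same build, and 51633 of the 51912 identifiers matched it. Longest transcripts of the 20 leading genes were searched against all annotated transcripts with BLAST 2.17.0 at 95% identity over 80% of their length, beside 300 random genes that also had a mean at or above the median and both libraries of a genotype above both of the other. Reads of overlapping or antisense genes cannot be told apart, since the libraries carry no strand information. Where a genotype had 0 counts in both libraries, a fold is a lower bound computed with 3 counts per library as the floor, and list medians with such genes at that bound were the same. List means of log2 changes are given with such genes at that bound, and the scale camera used is named where the mean on it differs in sign.

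Robo1 and Robo2 are always named. In each direction the rule takes up to 10 genes past the threshold with the largest change, both libraries of a genotype above both of the other and a mean at or above the median, filled with the smallest p where fewer pass. It adds up to 4 members of smallest p from each list, the most abundant member of each cell type list, and Ins1, Ins2, Gcg, Sst, Ppy, Ucn3 and Mafa. A further gene of the rule is not reported here and is not counted below. Predicted genes without a given name are left out of it. The rule allows 128 genes, of which the text names 99: 4 members of a list that passed camera or had at least 4 members with an unadjusted p under 0.05, and 2 of any other list. That narrowing was made after the values and the reversals under other settings were seen. Gm8797 and the genes of the families in the closing section fall outside the rule and were chosen after their values were seen. Robo3, Kdr, Cdh5 and Xist, list members that did not pass the filter, are also named outside the rule. Reversals over all genes of the rule are counted in the closing section.

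The fitting step was tested on simulated counts for the 16517 genes with the means, totals and dispersions of these libraries. At an adjusted p under 0.05 it called 20% of genes changed 2-fold, 84% changed 4-fold, 86% changed 8-fold and 98% changed 16-fold. Each share is of 50 genes, and 17 of 16317 unchanged genes were called. The changed genes were drawn from those at or above the median abundance, so changes in rarer genes were not covered. In the data Tpm3-rs7, 13.5-fold higher in the mutant libraries, did not pass in edgeR, so these shares may not hold here. A simulated list of 40 genes shifted 2-fold was called, and 0 of 20 unshifted lists were. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. In the 8 lists that passed camera, the estimated correlation ran from 0.042 (cholesterol synthesis) to 0.82 (acinar markers), above the preset 0.01.

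The alternatives for filter and scaling were no filter, a stricter filter, and equal-median, equal-total and quantile scaling. Further alternatives were DESeq2 1.42.0, robust moderation in edgeR, other thresholds, and leaving out each library in turn. Limma was run with a trend at pseudocounts of 0.1 and 5, and without a trend at a pseudocount of 1 alone. Limma with a trend at a pseudocount of 1, the newer dispersion moderation of edgeR and an acinar covariate were added after seeing the data. So were leaving out genes at 0 in a genotype and camera on count z-scores. The acinar covariate is the mean log2 level of the acinar markers, on which Robo mutant 2 stands highest. It therefore cannot separate acinar content from other differences of that library. Shares of a library's counts have Wilson 95% intervals. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.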

Results

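Messenger RNA was compared between sorted β cells of control mice and of mice with mutant alleles of the Roundabout receptor genes Robo1 and Robo2, at postnatal day 13, with 2 libraries per genotype. The series title gives the question as whether β cells need these receptors for endocrine cells to sort into the mature islet architecture. The totals were 48217557 and 38886129 counts in the control libraries and 49593712 and 47788000 in the mutant libraries. Across the 16517 tested genes, log2 CPM correlated at 0.977 between the control libraries and at 0.937, the lowest of the pairs, between the mutant libraries (Pearson, across genes, which are not independent replicates). The first principal component, with 51.8% of the variance, set Robo mutant 2 apart from the other libraries, and the second, with 31.3%, separated the genotypes.

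Both targeted transcripts were lower in both mutant libraries than in both control libraries. Robo1 (ENSMUSG00000022883, chromosome 16, 72308306 to 73046095, plus strand, GRCm38) stood at 76.3 ± 39.3 and 21.7 ± 0.893 CPM in control and mutant cells (SD, n = 2 each), a 3.52-fold lower level in the mutant. Its log2 change was -1.82 with a standard error of 0.40. Robo2 (ENSMUSG00000052516, chromosome 16, 73891839 to 74411825, minus strand, GRCm38) stood at 96.8 ± 30.5 and 29.2 ± 4.98 CPM (SD, n = 2 each), 3.32-fold lower, with a log2 change of -1.73 and a standard error of 0.28. By edgeR's quasi-likelihood test the unadjusted p was 0.0080 for Robo1 and 0.0024 for Robo2, and the adjusted p was 0.680 for both. DESeq2 gave adjusted p of 0.0019 and 1.99e-05. Without control 2 the log2 change of Robo1 was -1.16. Gene-level counts include exons outside a deleted part, so the remaining transcript does not measure remaining receptor.

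**Figure D1:**
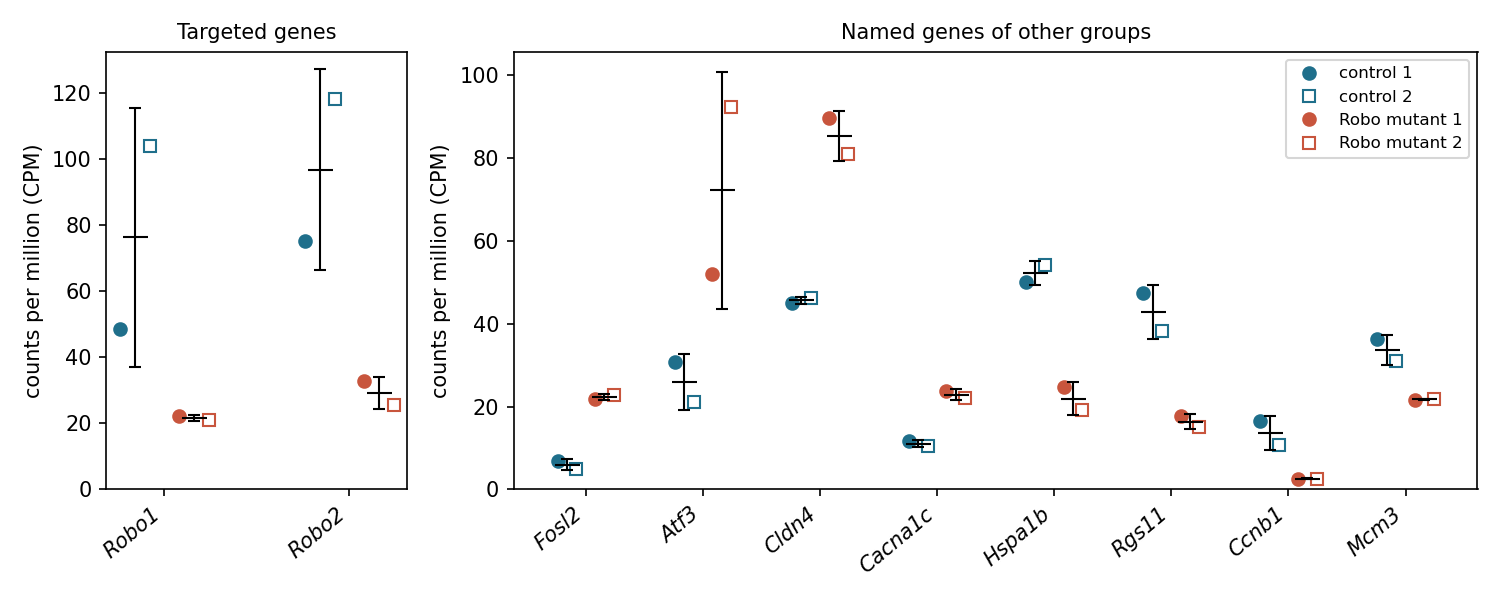
CPM of the targeted genes (left) and of 8 other named genes (right) in each library. Points are single libraries, horizontal bars are means of 2 libraries and whiskers are SD. Robo1 and Robo2 lie lower in both mutant libraries than in both control libraries, and 0 of the 16517 tested genes passed the adjusted threshold in edgeR.

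Beyond the receptors, the leading transcripts that were higher in both mutant libraries included the tight junction gene Cldn4 (chromosome 5, 134945119 to 134946934), the AP-1 factor gene Fosl2 (chromosome 5, 32135801 to 32157842), the endoplasmic reticulum chaperone gene Hyou1 and the surface antigen gene Cd24a. Those that were lower in both included Mgea5 (chromosome 19, 45750259 to 45783837), which encodes the enzyme removing O-GlcNAc from proteins, the G-protein regulator gene Rgs11 (chromosome 17, 26202951 to 26211324), the heat shock gene Hspa1b and the heparan sulfate proteoglycan gene Sdc3 (all GRCm38). Cldn4 was at 45.7 ± 0.831 and 85.3 ± 6.07 CPM in control and mutant cells, and Fosl2 at 5.95 ± 1.34 and 22.3 ± 0.777 CPM (SD, n = 2 each). Rgs11 was at 42.9 ± 6.49 and 16.3 ± 1.84 CPM, 2.63-fold lower, and Mgea5 at 164 ± 14.3 and 87.6 ± 0.469 CPM, 1.88-fold lower (SD, n = 2 each). The log2 changes of Cd24a and Sdc3 were 1.01 and -0.70.

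In edgeR none of these differences passed the test. DESeq2 called Cldn4 (adjusted p = 0.000303), Fosl2 (0.000381), Hyou1 (6.37e-08), Cd24a (0.0027), Mgea5 (1.60e-05), Rgs11 (0.000678) and Hspa1b (0.0010), but not Sdc3. Among the list members named below it called Gja1, Ncam2, Glp1r, Atf3, Hspa1a, Atf4, Ccnb1, Wwtr1, Lama4, Col4a6 and Itgam. With edgeR, 0 of 16517 genes had an adjusted p under 0.05, the smallest being 0.680. At an unadjusted p under 0.05 there were 1025 genes (329 higher, 696 lower), where 826 would be expected by chance. Of the lower ones 304 had 0 counts in both mutant libraries, and these were all the tested genes at 0 in both. The filter admits such genes only with at least 10 counts in both controls. Without genes at 0 in a genotype, 686 of 16192 genes had a p under 0.05. That exclusion follows the genotype labels and removes the 304 genes above, all with a p under 0.05. The number expected by chance therefore no longer applies to it, and it does not show whether an excess remains. Quantile normalization with limma put 529 of the 1088 genes with an unadjusted p under 0.05 on the higher side. DESeq2 called 151 genes (51 higher, 100 lower), of which 63 were at 0 in both libraries of a genotype. Limma without a trend called 133, of which 128 were at 0 in both libraries of a genotype. Without Robo mutant 2, edgeR called 1 gene, Gm8797, which is named because it was the call and was chosen after its values were seen. Its counts were 4556 and 3783 in control, 270 in mutant 1 and 4690 in mutant 2. In 36.6% of genes both libraries of a genotype lay above both of the other, against 33.3% by chance.

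The remaining leading genes were named by their smallest p and did not pass in edgeR, whereas DESeq2 called each of them, with adjusted p from 1.11e-25 (Hist1h2al) to 0.0151 (Rtn4rl1). Higher in both mutant libraries were Tpm3-rs7 (log2 change 3.75), Rps3a2 (2.59), Dbpht2 (0.93), Fam107b (1.23) and the RNA methyltransferase gene Nsun4 (1.44), and Hist1h2al stood at 0.125, 0, 27.0 and 26.4 CPM in control 1, control 2, mutant 1 and mutant 2. Lower were Hist2h2aa2 (-1.40), the importin gene Ipo13 (-1.31), the Y-linked Uty (-1.04), Csrp2bp (-0.77), the Nogo receptor homologue gene Rtn4rl1 (-0.84) and Kctd12b (-0.85). Rps3a2 and Hist1h2al are annotated as processed pseudogenes and Dbpht2 as a long noncoding RNA. Tpm3-rs7, Rps3a2, Hist1h2al and Hist2h2aa2 share near-identical sequence with other genes, between which reads can be divided, so their values are uncertain.

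Among axon guidance genes, Slit2 and Slit3, which encode Robo ligands, were lower in both mutant libraries. Slit2 was at 8.53 ± 7.38 and 1.11 ± 0.889 CPM and Slit3 at 4.75 ± 1.85 and 1.175 ± 0.0489 CPM in control and mutant cells (SD, n = 2 each). The log2 change of Slit2 was -2.94, with -1.58 without control 1 and -4.14 without Robo mutant 2. Of the 22 tested members of the Slit and Robo pathway, 16 were lower and 6 higher, and the list did not pass (camera of limma, adjusted p = 0.247). Robo3 had 0 counts in every library, which allows up to 3 counts each. Other guidance genes were divided, with 16 of 35 higher (camera, adjusted p = 0.829), among them the netrin gene Ntn4 (log2 change 0.88) and the ephrin receptor gene Ephb2 (1.11). The median of this list was -0.021 and its mean -0.035, while camera pointed up, relative to the other tested genes.

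Cell adhesion genes also lay on both sides, 21 of 39 higher and 18 lower (camera of limma, adjusted p = 0.829). Adjusted over the list alone, 2 members passed in edgeR, against 0 over all genes tested. These were Cldn4, higher in both mutant libraries, and Gja1, the gene of the gap junction protein connexin 43, with 163 and 193 counts in control and 0 in both mutant libraries, at least 64.6-fold lower. Ncam2, a neural adhesion molecule gene, had 61 and 111 counts in control 1 and control 2 and was also at 0 in both mutant libraries. It was at least 31.7-fold lower than the control mean. The integrin gene Itgav had a log2 change of -0.52. The mean log2 change of the list, with Gja1 and Ncam2 at their bounds, was -0.23 and its median 0.0485, and camera pointed up. Fry's mixed test, which asks for change in either direction, gave this list an adjusted p of 0.0059. Of the 25 lists only this 1 passed the mixed test, the next smallest adjusted p being 0.0989 for immune markers. The mixed test was not run without Gja1 and Ncam2. All 304 tested genes at 0 in both mutant libraries had an unadjusted p under 0.05 in edgeR.

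Insulin transcripts took 20.0064% and 17.5076% of counts in the control libraries, 20.0185% in mutant 1 and 12.7533% in mutant 2 (Wilson 95% intervals 19.9951% to 20.0177%, 17.4956% to 17.5195%, 20.0074% to 20.0297% and 12.7438% to 12.7627%). Insulin transcripts took their lowest share in the library with the most acinar transcripts. The log2 changes of Ins1 and Ins2 were -0.11 ± 0.21 and -0.16 ± 0.23 (SE, n = 2 each). Ucn3 (0.25), a marker of maturing β cells, and the factor gene Mafa (-0.31) also differed by less than the test could separate. Of 35 genes of β-cell identity and function, 25 were lower and 10 higher, with a median log2 change of -0.17 (camera of limma, adjusted p = 0.0767). Both mutant libraries lay below both controls in 14 members and above both in 6. The median deviation from the mean of the 4 libraries was 0.059 in control 1 and 0.10 in control 2. It was 0.033 in mutant 1 and -0.13 in mutant 2, the library with the most acinar transcripts. This list passed without control 1 (0.0044), under a stricter filter (0.0253), under quantile normalization (0.000151) and without genes at 0 in a genotype (0.0251), each an adjusted p by camera. With all libraries it gave adjusted p = 0.666 with an estimated correlation and 0.690 by fry's directional test. The incretin receptor genes Gipr (-0.48) and Glp1r (-0.48) had its smallest p, 0.0157 and 0.0246 unadjusted in edgeR, and DESeq2 called Glp1r (adjusted p = 0.0339).

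Maturation genes were lower in 15 of 24 cases (camera of limma, adjusted p = 0.212, or 0.786 with an estimated correlation). The PACAP receptor gene Adcyap1r1 had 11 and 79 counts in control 1 and control 2 and 0 in both mutant libraries. It was at least 17.2-fold lower than the control mean, a bound that rests mostly on control 2. Genes of immature β cells or disallowed in mature ones were lower in 16 of 30 (camera, adjusted p = 0.586), with the hexokinase gene Hk1 at a log2 change of -1.82 and the transcription factor gene Maf at 0, 0.0245, 0.220 and 0.946 CPM in control 1, control 2, mutant 1 and mutant 2. Genes of exocytosis and excitability were lower in 19 of 31 (camera, adjusted p = 0.872). Cacna1c, a pore subunit gene of L-type calcium channels, had a log2 change of 1.05 with a standard error of 0.23, and Unc13a, a vesicle priming gene, one of -0.56.

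Transcripts of the other endocrine cells were present in all libraries. Gcg, the glucagon gene, was at 17254 ± 8206 and 21028 ± 3492 CPM in control and mutant cells, the somatostatin gene Sst at 752 ± 57.3 and 1474 ± 949 CPM and the pancreatic polypeptide gene Ppy at 1994 ± 847 and 1552 ± 1080 CPM (SD, n = 2 each). Alpha-cell markers were higher in 11 of 14 cases (camera of limma, adjusted p = 0.0663), including Etv1 (log2 change 0.68) and Dpp10 (1.09). Without Robo mutant 1 the log2 change of Dpp10 was 0.33 and that of Sst went from 0.97 to 0.096. This list passed without control 1 (2.80e-07), without a filter (0.0235), with equal totals (0.0446) and without genes at 0 in a genotype (0.0481), and pointed down without control 2 (0.705). With all libraries it gave adjusted p = 0.666 with an estimated correlation. Delta-cell markers were higher in 7 of 9 (camera, adjusted p = 0.4725), including Rbp4 (0.64) but not the somatostatin receptor gene Sstr3 (-0.38), with a median of 0.64 and a mean of 0.18, or -0.30 on the scale camera used. Camera pointed up. The delta list pointed down without Robo mutant 1, at 0.846. Markers of PP and epsilon cells were higher in 3 of 4 (camera, adjusted p = 0.129, or 0.0016 without control 1 and 0.666 with an estimated correlation), with Pyy at 0.42 and Tspan8 at 0.65.

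**Figure D2:**
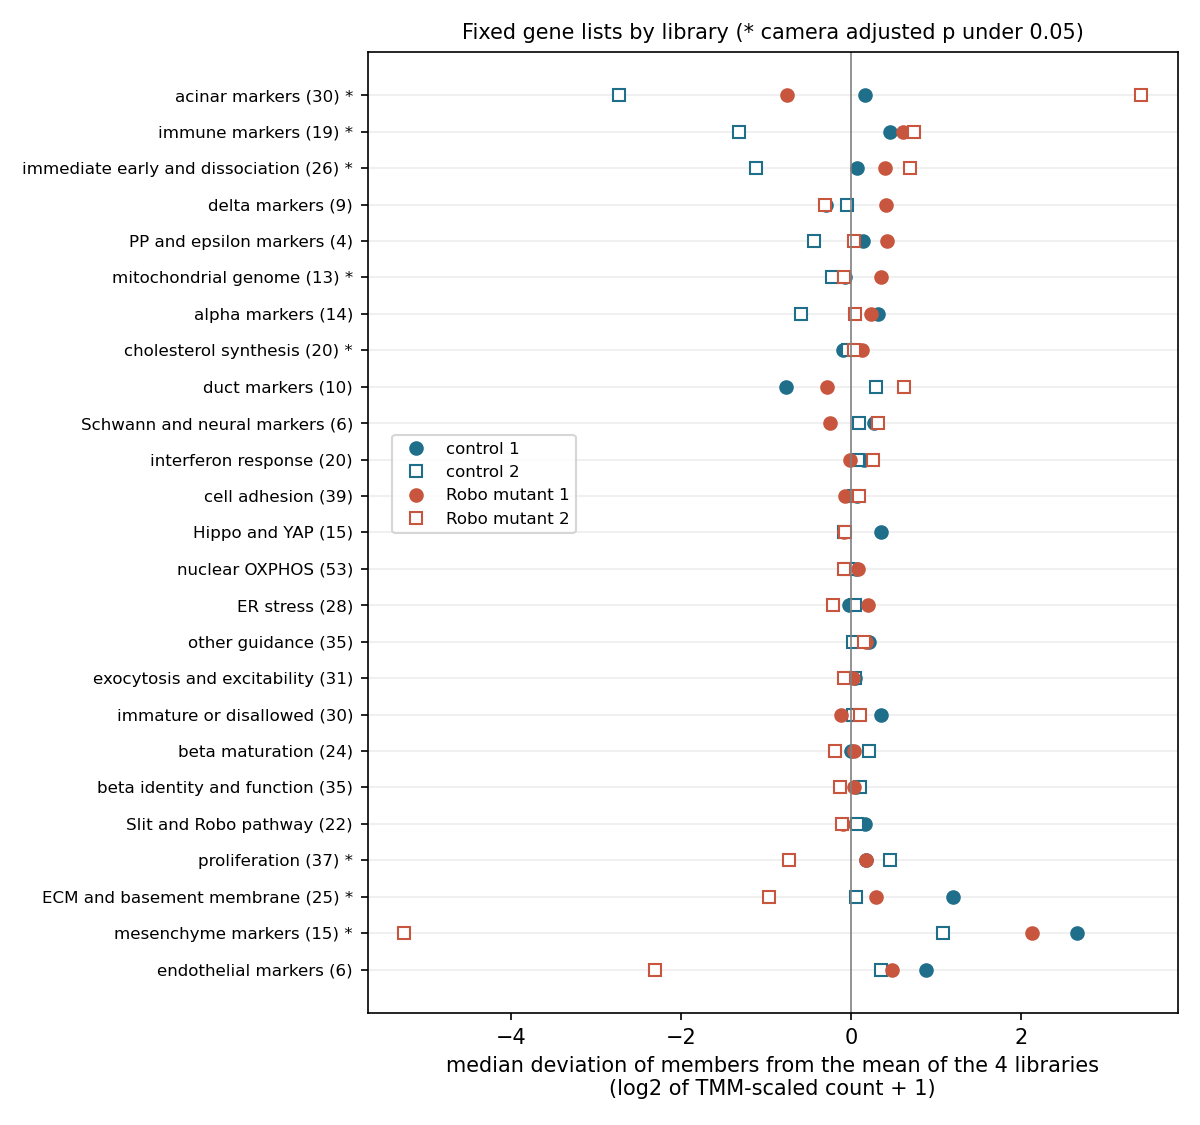
Median deviation of each fixed list's members from their mean over the 4 libraries, in log2 of the TMM-scaled count plus 1, for each library, with the number of tested members in brackets. Lists are ordered by their median log2 change, and an asterisk marks an adjusted p under 0.05 by camera with a preset correlation. The immediate early list spans -1.12 in control 2 to 0.69 in mutant 2, and the mesenchyme list reaches -5.255 in mutant 2.

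Immediate early and dissociation-response genes rose as a list in the mutant libraries. Of 26 members, 24 were higher, 17 of them in both mutant libraries above both controls, and the median log2 change was 0.94 (camera of limma, adjusted p = 3.64e-09). The adjusted p was 0.666 with an estimated correlation. The call with the preset correlation held without each library in turn, and control 2 was the lowest library for the list. Fosl2 and the stress factor gene Atf3 (1.48) were higher, whereas the heat shock genes Hspa1b (-1.26) and Hspa1a (-1.85) were lower in both mutant libraries, a pair with similar coding sequences whose single values are uncertain. Adjusted over the list alone, Fosl2 and Hspa1b passed in edgeR, 2 members against 0 over all genes tested. In the other lists tested as sets 0 members passed when adjusted over the list alone, apart from the cell adhesion genes.

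In the list of endoplasmic reticulum stress, 14 of 28 members were higher and 14 lower (camera of limma, adjusted p = 0.203, or 0.0148 without Robo mutant 2, 0.0033 with an acinar covariate and 0.666 with an estimated correlation). Hyou1 was 2.25-fold higher (log2 change 1.17 ± 0.18, SE, n = 2 each), and Atf4 (0.70) and Ddit3 (0.99), factor genes of the integrated stress response, were also higher. Eif2ak3, the gene of the kinase PERK, was lower (-0.63). The median of the list was -0.012 and its mean 0.27, and camera pointed up, but down without Robo mutant 1 (adjusted p = 0.649).

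Genes of cholesterol synthesis rose as a list, 16 of 20 being higher with a median log2 change of 0.23 (camera of limma, adjusted p = 0.0073). The adjusted p was 0.666 with an estimated correlation. The pathway enzyme genes Idi1 (0.97), Hmgcs1 (0.75), Msmo1 (0.48) and Cyp51 (0.44) had the smallest p. Genes of the mitochondrial genome rose too, 11 of 13 being higher with a median of 0.33 (camera, adjusted p = 0.000421, and adjusted p = 0.666 with an estimated correlation), including mt-Atp6 (0.48), mt-Nd6 (0.46), mt-Nd4 (0.39) and mt-Co1 (0.28). Without Robo mutant 1 both calls were lost, at adjusted p of 0.3405 and 0.409, and the mitochondrial call was lost under quantile normalization, at 0.194. Of the nuclear genes of oxidative phosphorylation, 25 of 53 were higher (camera, adjusted p = 0.803), among them Cox5a (0.27) and Ndufa4 (0.28). Their median was -0.0092 and their mean -0.011, while camera pointed up.

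Proliferation genes fell as a list, mostly through Robo mutant 2. Of 37 members 27 were lower, 17 of them in both mutant libraries below both controls, and the median log2 change was -0.62 (camera of limma, adjusted p = 0.000775). The adjusted p was 0.666 with an estimated correlation. Ccnb1, the gene of the mitotic cyclin B1, was at 13.6 ± 4.04 and 2.54 ± 0.1105 CPM in control and mutant cells (SD, n = 2 each). The kinetochore gene Cenpe (-1.40) and the replication helicase genes Mcm3 (-0.63) and Mcm7 (-1.02) followed. Summed, the list stood at 1415, 1529, 1617 and 1263 CPM in control 1, control 2, mutant 1 and mutant 2. The median log2 difference from the control mean was -0.16 in mutant 1 and -1.11 in mutant 2. The call was lost without Robo mutant 2, the library with the most acinar transcripts. It was also lost with an acinar covariate (camera, adjusted p = 0.906), which cannot separate acinar content from other differences of mutant 2.

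In the Hippo and YAP list 8 of 15 were higher (camera of limma, adjusted p = 0.4725), while the coactivator gene Wwtr1, at 4.72, 4.98, 0.160 and 0 CPM in control 1, control 2, mutant 1 and mutant 2, and Cyr61 (log2 change -0.58) were lower. Its mean was -0.31 and its median 0.030, and camera pointed down. In the interferon list 11 of 20 were higher (camera, adjusted p = 0.872), with the histocompatibility gene H2-K1 at 0.21 and Oasl2 at -1.07. Its mean was -0.19 and its median 0.052, and camera pointed down.

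Extracellular matrix and basement membrane genes fell as a list, 21 of 25 being lower with a median log2 change of -0.65 (camera of limma, adjusted p = 0.0013). The adjusted p was 0.666 with an estimated correlation. The laminin gene Lama4 (-2.33) and the protease inhibitor genes Timp2 (-0.46) and Timp3 (-0.83) were lower. The collagen gene Col4a6 had 264 and 58 counts in control 1 and control 2 and 0 in both mutant libraries. It was at least 55.1-fold lower than the control mean, a bound that rests mostly on control 1. Mesenchyme markers fell as well, 13 of 15 being lower with a median of -1.06 (camera, adjusted p = 0.0050, and adjusted p = 0.666 with an estimated correlation). The collagen gene Col3a1 was at 1338, 426, 615 and 8.93 CPM and Col1a2 at 424, 122, 94.5 and 1.89 CPM in control 1, control 2, mutant 1 and mutant 2. Fbln1 (-1.06) and Lum (-1.33) were likewise lowest in mutant 2. Without Robo mutant 2 neither list passed, at an adjusted p of 0.652 for both and with the mesenchyme list pointing up, and mutant 2 is the library with 9.70% acinar transcripts. Without control 1 the matrix list gave 0.282, and with an acinar covariate the mesenchyme list gave 0.540.

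Acinar transcripts, which encode the digestive enzymes of the exocrine pancreas, made up 1.09% of counts in control 1 (Wilson 95% interval 1.09% to 1.09%), 0.142% in control 2 (0.141% to 0.144%), 0.565% in mutant 1 (0.563% to 0.567%) and 9.70% in mutant 2 (9.69% to 9.71%). As a list they rose, 29 of 30 being higher with a median log2 change of 3.05 (camera of limma, adjusted p = 3.64e-09). The adjusted p was 0.666 with an estimated correlation, and 0.0795 without Robo mutant 2, which decides the call. In 4 of the 30 both mutant libraries lay above both controls. Pnliprp1 was the most abundant, at 2298, 196, 834 and 21364 CPM in control 1, control 2, mutant 1 and mutant 2, and Try4 (4.01), Amy2a5 (3.52), Pnlip (2.22) and Ctrc (4.11) had the smallest p. Without Robo mutant 2 these were 1.90, 1.24, 2.27 and 0.51. Try4 and Amy2a5 belong to multigene families with similar members, so their single values are uncertain.

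**Figure D3:**
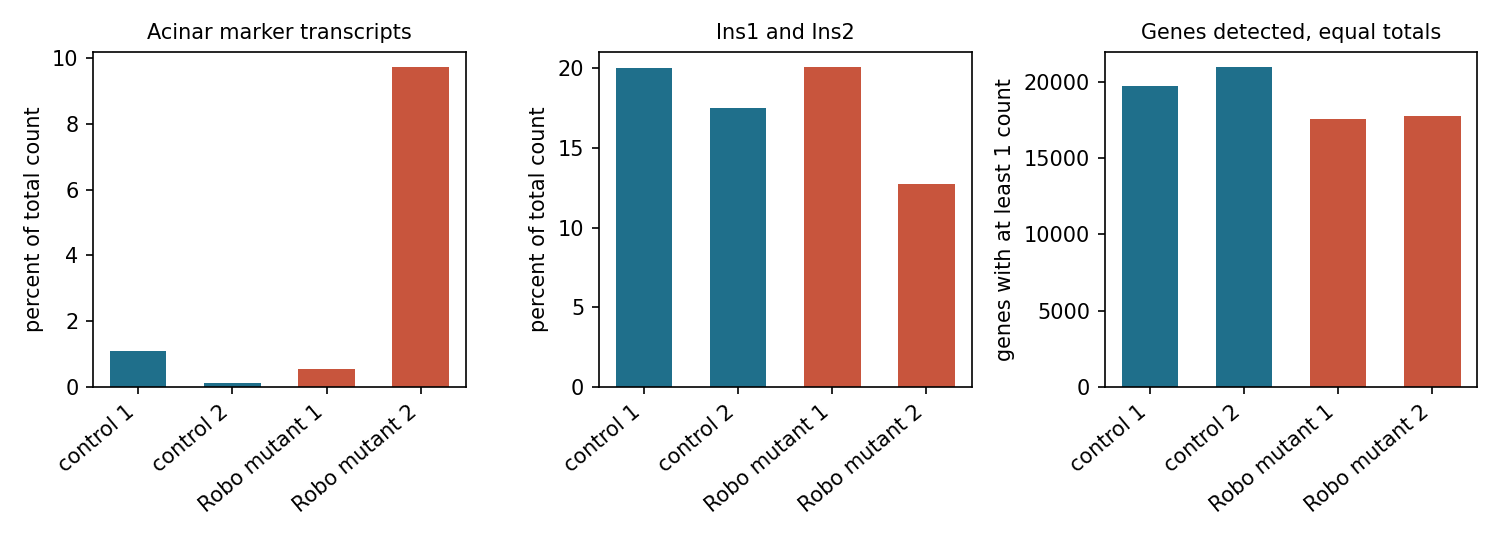
Percent of the total count in the acinar marker list (left) and in Ins1 and Ins2 (middle), and genes with at least 1 count after thinning every library to the smallest total (right), per library. Robo mutant 2 holds 9.70% acinar and 12.7533% insulin transcripts, and the mutant libraries detect 17580 and 17771 genes against 19712 and 20918 in control.

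Immune markers rose as a list, 17 of 19 being higher with a median log2 change of 1.10 (camera of limma, adjusted p = 0.000205). The adjusted p was 0.666 with an estimated correlation, and the call was also lost without control 2 (0.1245) and without Robo mutant 2 (0.1575), and with an acinar covariate (0.465). The complement gene C1qb (1.76), Laptm5 (1.38) and Fcer1g (1.10) were higher in both mutant libraries, C1qb at 2.82 without control 1 and 1.16 without control 2 and Laptm5 at 2.07 without control 1. Cd74 was the most abundant (0.61), but its log2 change was 2.62 without control 1, -0.20 without control 2 and -1.555 without Robo mutant 2. The integrin gene Itgam was at 0 in both controls, with 170 and 81 counts in mutant 1 and mutant 2. Its mutant mean was at least 38.0-fold higher. Endothelial markers were lower in 5 of 6 (camera, adjusted p = 0.199, or 0.0271 without a filter and 0.666 with an estimated correlation), with Egfl7 at -1.36 and the most abundant, Esam, at -0.014. Plvap was at 0.355, 4.785, 0.260 and 0.154 CPM in control 1, control 2, mutant 1 and mutant 2, so control 2 decides its log2 change of -3.61, which was -0.77 without that library. Kdr and Cdh5, which did not pass the filter, had 107 and 77 counts in control 2, 0 and 6 in control 1 and 0 in both mutant libraries. Duct markers were higher in 7 of 10 (camera, adjusted p = 0.242), with Tff2 at 2.45, Dcdc2a at 0.76 and the most abundant, Krt7, at -0.089. The duct list passed without control 2 (0.0031) and without Robo mutant 1 (0.0098), and pointed down without control 1 (0.527) and without Robo mutant 2 (0.743). With all libraries it gave adjusted p = 0.786 with an estimated correlation. Schwann and neural markers were higher in 4 of 6 (camera, adjusted p = 0.959), with Sox10 at 0.44 and Erbb3, the most abundant, at -0.25. Their mean was 0.15, or -0.27 on the scale camera used, and their median 0.11, and camera pointed down. Of the erythroid markers 0 passed the filter.

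On chromosome 16, 3 of 481 tested genes besides Robo1 and Robo2 (0.624%) had an unadjusted p under 0.01, against 158 of 15415 (1.025%) on the other autosomes (two-sided Fisher's exact test, odds ratio 0.606, 95% interval 0.123 to 1.81, p = 0.639). The odds ratio was 1.18 without Robo mutant 1, 1.33 without Robo mutant 2 and 0 without either control. Within 20 Mb of Robo1 or Robo2, these 2 left out, 1 of 116 genes had a p under 0.01 (two-sided Fisher's exact test, odds ratio 0.849, 95% interval 0.0212 to 4.89), and 10 (8.62%) one under 0.05, against 6.08% of other autosomal genes (two-sided Fisher's exact test, odds ratio 1.46, 95% interval 0.677 to 2.80, p = 0.241). Both intervals are wide, so more frequent differences near the targeted genes are not excluded. Xist had 0 or 1 count in each library, and Y-linked transcripts were present in all 4. Uty was at 47.4 ± 0.533 and 23.0 ± 2.46 CPM in control and mutant cells (SD, n = 2 each), while Eif2s3y had a log2 change of -0.29.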

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

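Limma with a trend at a pseudocount of 1, the newer moderation of edgeR and the acinar covariate were chosen after seeing the data. So were leaving out genes at 0 in a genotype and camera on count z-scores. No paired analysis was possible because the replicate numbers follow accession order and pair no libraries. When a library was left out, the lone library of its genotype was assumed to vary like the others. The biological coefficient of variation was 61.2%, with 2 libraries per genotype. The simulated libraries gave 10 calls for 50 genes changed 2-fold, so changes of that size can go uncalled. Larger ones can too, since Tpm3-rs7 was 13.5-fold higher in the mutant libraries and did not pass in edgeR. Why results differ between the settings below was not tested, except that an unadjusted threshold admits more genes by construction.

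No gene passed in edgeR, with or without a filter, under equal-median or equal-total scaling, with robust or newer moderation or with the acinar covariate, nor in limma with a trend. The count was 1025 at an unadjusted p under 0.05, 151 with DESeq2, 133 with limma without a trend, and 0 to 1 when a library was left out. Robo1 and Robo2 were lower under every setting run, and past the threshold with DESeq2, at log2 changes of -1.80 and -1.71. The number of lists past the threshold was 8 with camera, 0 with an estimated correlation, 0 with fry's directional p, 5 with the acinar covariate, and 4 (without Robo mutant 2) to 11 (without control 1) when a library was left out. The odds ratio of chromosome 16 genes ran from 0 to 1.33 when a library was left out. Among matched random lists, the medians of the 8 lists called by camera lay at percentile 0 or from 99.98 to 100. For the other lists they ran from 0.05 (β-cell identity and function) to 99.72 (delta-cell markers). Random lists do not hold the correlation between members, so an extreme percentile is not a call.

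Over the 25 lists, 17 results in 7 lists pointed the other way under other settings and 16 in 12 lists when a library was left out. Adjusted p of reversed lists were, with fry, 0.985 for other guidance, 0.690 for adhesion and 0.976 for oxidative phosphorylation. With quantile normalization they were 0.928, 0.778 and 0.727 for the same lists and 0.508 for Schwann markers. With the acinar covariate they were 0.465 for other guidance, 0.502 for adhesion, 0.810 for maturation and 0.906 for exocytosis. Schwann markers gave 0.992 on count z-scores, 0.906 with equal totals and 0.963 at a pseudocount of 5. Oxidative phosphorylation gave 0.746 with equal totals, exocytosis 0.967 without a filter and interferon 0.961 with a stricter filter.

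Leaving out a library gave adjusted p from 0.469 to 0.7145 for other guidance, 0.386 to 0.705 for adhesion, 0.381 to 0.8455 for exocytosis, 2.80e-07 to 0.705 for alpha cells and 0.131 to 0.846 for delta cells. It gave 0.0031 to 0.743 for duct, 1.17e-13 to 0.652 for mesenchyme, 0.649 to 0.8455 for Schwann markers and 0.0148 to 0.649 for endoplasmic reticulum stress. For oxidative phosphorylation it gave 0.162 to 0.532, for Hippo 0.0879 to 0.8455 and for interferon 0.231 to 0.8455.

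Of the genes the rule gives besides Robo1 and Robo2, 126 were followed. Under other settings 24 values in 14 genes changed sign or became 0, and 23 in 18 genes when a library was left out. None of those genes had passed in edgeR. Under other settings 32 values in 30 genes became calls, 30 of them with DESeq2 and the others, Gja1 and Itgam, with limma without a trend. With quantile normalization the log2 change was -0.20 for Pyy, 0.0088 for Esam and 0.00 for Ins1 and Ins2, which held the highest counts of every library, in the same order, and are set equal by that method. Esam gave 0.0052 with a stricter filter and 0.0044 with DESeq2. With the acinar covariate the values were -0.083 for Gcg, -0.35 for Pnliprp1, -0.79 for Tff2, -1.55 for Cd74, 0.43 for Erbb3 and 0.019 for Ins1.

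Of 94 named genes with counts in both genotypes, Robo1 and Robo2 included, 28 had a fold that moved by over 1.5 times when a library was left out, none of them called by edgeR. Leaving out a library gave log2 changes from -0.13 to 0.88 for Gcg, -1.34 to 0.22 for Ppy, -0.58 to 5.83 for Pnliprp1, -0.87 to 3.97 for Tff2 and -0.084 to 1.29 for Dcdc2a. The ranges were -0.58 to 0.42 for Esam, -1.555 to 2.62 for Cd74, -1.55 to 0.43 for Erbb3 and -0.68 to 0.0097 for Eif2s3y. They were -0.48 to 0.10 for Ins2 and -0.39 to 0.13 for Ins1. For Robo1 and genes that kept their sign they were -2.26 to -1.16 for Robo1, -4.14 to -1.58 for Slit2, 0.33 to 1.59 for Dpp10, 0.096 to 1.51 for Sst and -4.51 to -0.77 for Plvap. Acinar genes gave 1.90 to 5.19 for Try4, 1.24 to 4.37 for Amy2a5, 1.74 to 2.93 for Pnlip and 0.51 to 5.81 for Ctrc, and mesenchyme and endothelial genes -7.17 to -1.34 for Col1a2, -6.63 to -0.45 for Col3a1, -4.05 to -0.14 for Lum, -2.19 to -0.43 for Fbln1 and -2.42 to -0.76 for Egfl7. The others gave 1.16 to 2.82 for C1qb, 0.92 to 2.07 for Laptm5, -2.64 to -1.34 for Hspa1a and -1.80 to -0.59 for Oasl2. Hist1h2al, Maf and Wwtr1, at or near 0 in 1 genotype, are given per library instead.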

Other observations

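All families and tests in this part were chosen after the patterns were seen, and for chromosome 14 alone the bound was set before its value was computed. Of 121 groups of genes sharing a name stem, with at least 12 tested members each, 5 passed camera of limma with the preset correlation, and each had an adjusted p = 0.948 with an estimated correlation. The stem Rps also covers S6 kinase genes, and 3 of these stems cover pseudogenes or genes of other proteins, so the values of Rpl, Rps and Col below leave out 2, 14 and 1 such members. Large ribosomal subunit genes with their homologues (Rpl) were higher in 42 of 46 (median log2 change 0.25, adjusted p = 2.10e-09) and those of the small subunit (Rps) in 30 of 32 (0.25, 2.16e-06). Both mutant libraries lay above both controls in 25 of the Rpl and 16 of the Rps genes. Summed, Rpl stood at 3289, 2936, 3494 and 4039 CPM and Rps at 1932, 1629, 1929.5 and 2260.4 CPM in control 1, control 2, mutant 1 and mutant 2. Single ribosomal protein genes share sequence with pseudogenes, so their own values are uncertain. Dual-specificity phosphatase genes (Dusp) were higher in 15 of 20 (0.39, 5.78e-05), with Dusp6 at 19.9 ± 2.05 and 44.5 ± 5.87 CPM and Dusp4 at 12.1 ± 0.192 and 33.9 ± 11.2 CPM in control and mutant cells (SD, n = 2 each). Krüppel-like factor genes (Klf) were higher in 13 of 15 (0.50, 0.0057), with Klf10 at a log2 change of 1.04, and collagen genes (Col) were lower in 29 of 36 (-0.97, 0.000327). Dusp1, Klf2, Klf4 and Klf6 also belong to the immediate early list. The medians kept their sign with equal-median, equal-total and quantile scaling and without each library in turn, the collagen median running from -2.95 without Robo mutant 1 to -0.24 without control 1. Of the collagen genes 5 also belong to the mesenchyme list and 5 to the matrix list, and the sum of all 36 stood at 2867, 1115, 1355 and 307 CPM in control 1, control 2, mutant 1 and mutant 2.

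Acinar transcripts were highest in Robo mutant 2, with a median of 15.8-fold the control mean over 26 markers with a mean of at least 10 CPM (0.877 to 33.3), Pnliprp1 reaching 21364 and Amy2a5 9532 CPM. RNA carried over from 1 source should keep the ratios of the markers, and the SD over them of the log2 difference between mutant 2 and control 1, the libraries highest in them, was 0.84, which leaves carry-over from acinar cells open. Both mutant libraries lay above both controls in 13.3% of the 30 markers. In 23 of the 26 markers the order from low to high was control 2, mutant 1, control 1 and mutant 2. Mutant 1 thus lay between the controls in most markers and showed no rise above both. With 2 libraries per genotype, an added effect of the genotype cannot be told apart from a difference of mutant 2. The sort for mCherry should remove whole acinar cells, and free RNA or attached cells were not tested. Another fixed list holds 0 of the 30 markers, and 18 were at 10 CPM or more in every library.

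Of the 20 leading genes, 4 had a near-identical copy, against 1.67% of random genes (two-sided Fisher's exact test, p = 0.00116). Hist2h2aa2 is itself a copy of Hist1h2al, so these 4 are not independent and that p can be too small. Summed with its copies, Tpm3-rs7 moved by 0.0530 and Hist1h2al, whose copies include Hist2h2aa2, by 0.0204 on the log2 scale, which is consistent with reads divided differently between copies, as a sequence variant might cause. The sum for Hist2h2aa2 without Hist1h2al moved by -0.41, and that for Rps3a2 by 0.362, which for Rps3a2 leaves both a division of reads and a change of the gene open. Tpm3-rs7 and Rps3a2 lie on chromosome 14, whose genes had an odds ratio of 0.5496 for p under 0.01 (95% interval 0.112 to 1.64, Fisher's exact test). That interval includes 1 and gives no sign of a difference along the chromosome, and a short segment stays open because it would hold too few genes to move the ratio.

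Fewer genes were detected in both mutant libraries. After thinning to equal totals the lowest control still exceeded the highest mutant by 1941 genes, against 1982 before. Control 2 had the smallest total and the most genes detected, so thinning could hardly have closed the gap. The deposited total count therefore does not account for it, but sequencing depth stays open if the libraries were rescaled earlier. Genes at 0 in 1 library with at least 10 counts in the other of its genotype numbered 623 and 436 in control and 1203 and 1070 in the mutant, a ratio of at least 1.72, and random loss of rare transcripts stays open. For the proliferation list, the median lay at percentile 6.38 of abundance-matched random lists in mutant 1 and 0 in mutant 2. Whether such loss is the whole cause of the lower list cannot be told apart from an effect of genotype, because the libraries differ and there are 2 per genotype. An effect of the genotype itself was not tested separately.

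The genotypes gave 1025 genes with an unadjusted p under 0.05 in edgeR, and the highest of the other splits of the 4 libraries gave 583. In 1 of 3 splits, the real one included, the count was as large, and 3 splits are too few for a share under 0.05. Of the 1025 genes, 304 were at 0 in both mutant libraries. Without genes at 0 in a genotype the genotypes gave 686 of 16192 genes, and the other splits were not counted that way.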
